A study of Arabidopsis thaliana with 8 samples.

How the data were processed

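The series holds RNA sequencing of shoots and roots of Arabidopsis thaliana, ecotype Col-0, after exposure to 2,5-dimethylpyrazine, called 2,5-D here. This compound is a volatile pyrazine that microbes release. It was given at 100 µM on a paper disc in divided plates, with water on the disc of the controls. Per the labels, the exposure lasted 24 hours; the same labels also name 14 days of growth together in the plates before harvest, so the length of contact with the compound is not settled by them. Each of the 4 groups (shoot water, shoot 2,5-D, root water, root 2,5-D) had 2 libraries, 8 in all, made from total RNA with a DNBSEQ kit, per the labels' protocols. Nothing in the labels says that replicate libraries came from separately grown plants, so p-values measure the spread between these libraries, which may be technical.

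Reads were aligned with HISAT2 version 2.0.4, per the submitters' processing notes. The genome build, the annotation and the program that made the expression values are not given in the sources used here. The deposited values are a normalized expression signal per gene, with no unit in the file headers, in one table for shoots and another for roots. Each table lists the same 3691 genes, all of which matched a locus tag of the RefSeq annotation of assembly TAIR10.1. That annotation was used for gene symbols, product names and exonic lengths only, and no coordinates are given because the authors' build is not known. The authors' rule for choosing the listed genes is not given in the sources used here. Of the listed genes, 2 failed to separate both 2,5-D libraries from both water libraries in at least 1 tissue, while chance alone would leave 1640.4 (44.4%). The tables are therefore treated as lists picked on these same libraries. Calls below are calls within the listed genes and are not independent evidence of a response. No set test or enrichment of the response to 2,5-D was run on them. A comparison with random lists was made only for the difference between the shoot water libraries.

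The low values seemed to fall on steps. For each library, a step size and a length allowance were searched for that best fitted its low values. Multiplied by exonic length less the allowance, 72.3% to 86.9% of these same values lay within 0.1 of a whole multiple of the fitted step. The chance share of 20.0% holds for a step fixed beforehand. The share for the best of many steps tried was not computed. The search chose the same allowance, 250 bases, in every library. The values were thus taken as scaled by length and depth, as FPKM and TPM both are. Which of these the authors deposited could not be settled. From the fitted steps, the libraries' relative depth was estimated at 83.9% to 100% of the deepest. By the same estimate, 1 read was worth 0.0575 to 0.0685 for a gene of 1000 effective bases. Total depth is unknown.

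In the shoot table both 2,5-D columns carry the same header, replicate 1. They were used as the pair of 2,5-D shoot libraries, and their numbers 1 and 2 below follow the column order as names only. No column of per-sample values was left unused.

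For each tissue, values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend and treatment as the single term, among genes with a mean of at least 1 over the tissue's 4 libraries. P-values were adjusted by the Benjamini-Hochberg method and genes past an adjusted p of 0.05 were called, with no fold limit. Every adjusted p below comes from limma unless stated. Log2 changes are on the log2(value + 1) scale, which understates the change of genes with low values. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so no permutation p is given. Calls were also counted after adjustment over each gene list alone. On simulated values with the real genes' means and spreads, the root fit (3476 genes) recovered 98.0% of genes changed by 1 on the log2 scale and 100% of those changed by 2, with 12 false among 207 calls. The shoot fit (3370 genes) recovered 24.2% and 86.9%, with 6 false among 116 calls. The simulation changed 99 genes by 1 and 98 by 2 in root, and 99 by each in shoot. In the real root table limma called 2143 of 3487 tested genes. In the real shoot table the water pair varied more than the treated pair, with 553 and 14 genes over 2-fold apart. These recovery and false call rates belong to the simulated setting and may not hold for the real tables.

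The gene lists were fixed before the data were examined: nitrate transport, ammonium transport, nitrogen assimilation, nitrate signalling, auxin response, auxin synthesis and transport, cell wall loosening, cytokinin response, jasmonate, salicylate and immunity, abscisic acid with cold and drought, ethylene, heat shock, xenobiotic detoxification, iron deficiency, iron storage, phosphate starvation, sulfur starvation, photosynthesis, root tissue markers, circadian clock, glucosinolate synthesis, flavonoid synthesis, hypoxia, and sugar transport. The photosynthesis and root marker lists also served as markers of the other organ. Named genes followed a rule fixed at the same time. It took every listed nitrate or ammonium transport gene. It also took the 8 called genes with the largest rise and the 8 with the largest fall in a tissue. These needed a mean of at least 10 in the higher group and no overlap between groups. From each other list with at least 2 calls it took up to 4 calls with the smallest p. The text names 4 from lists with 6 or more calls and 2 from the rest, a split not in the fixed rule. The values of 1 gene that this rule would name are not reported here. Shoot genes outside the transport lists were chosen after their values were seen. A further list, of genes induced within minutes by touch or wounding, was written after the difference between the shoot water libraries was seen, without the genes that had shown it.

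The alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, rescaling of the libraries to equal medians, a fold limit, the replicate number as a block (root only) and leaving out each library. The medians in that rescaling are those of listed genes, treated as picked for differing, so equal medians are not a neutral scale. The planned set tests with either correlation and alternatives for count data were not run. Library weights and removal of each library's trend against exonic length (lowess over 0.5 of the genes) were added after seeing the data. So were gene families by product name and a tissue by treatment term fitted to the 8 libraries. The plan had allowed this term only for raw counts in both tissues, which these values are not. It takes 1 spread per gene for all groups, though the shoot water pair varied more than the rest. Families of near-identical genes, among them LHCB1, RBCS, AOC, the small heat shock proteins and tandem GSTU genes, can share reads, and how the authors' counting split them is not known, so values of single members are uncertain. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.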

Results

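Transcript abundance was measured in shoots and roots of Arabidopsis plants exposed to water or to the microbial volatile 2,5-D at 100 µM, with 2 libraries per group. The deposited tables give a normalized abundance for 3691 listed genes in each tissue. Values of the listed genes totalled 252869.9 to 343912 per library, and by the fitted steps libraries were within 83.9% to 100% of the deepest. Replicates correlated across genes at r = 0.988 (root water), 0.996 (root 2,5-D), 0.995 (shoot 2,5-D) and 0.946 (shoot water) on the log2 scale. The shoot water pair was over 2-fold apart in 553 genes, against 32, 2 and 14 in the root water, root 2,5-D and shoot 2,5-D pairs. The variance between replicates was 5.79 to 45.3 times counting noise, as estimated from those steps. Values are given as mean ± SD with n = 2.

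The series asks how 2,5-D affects genes that move nitrate and ammonium. In roots, the transcript of NRT1.5 (AT1G32450), which loads nitrate into the xylem for transport to the shoot, fell with 2,5-D, from 293 ± 90.2 to 111 ± 19.4 (log2 change -1.37, SE 0.23, adjusted p = 0.00112). NRT1.9 (AT1G18880), a nitrate transporter of the root phloem, fell as well (59.5 ± 12 in water and 28.1 ± 1.13 with 2,5-D, log2 change -1.04, adjusted p = 0.00130), as did SLAH1 (AT1G62280), a homologue of the SLAC1 anion channel (2.21 ± 0.184 in water and 0.395 ± 0.0778 with 2,5-D, log2 change -1.2, adjusted p = 0.000791). In the other direction, NRT2.1 (AT1G08090), a main carrier of high-affinity nitrate uptake, rose from 3.35 ± 0.460 to 7.51 ± 0.269 (log2 change 0.97, adjusted p = 0.00128), and AMT1;1 (AT4G13510), a high-affinity ammonium transporter, rose from 24.2 ± 0.672 to 45.0 ± 9.55 (log2 change 0.85, adjusted p = 0.00316).

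Of the 28 nitrate transport genes of the list, 8 were in the tables and 7 were tested in root: 1 rose, 3 fell and 3 did not pass. Of 6 ammonium transporters, 2 were in the tables, and 1 rose. The counts adjusted over the list alone were the same (1 higher and 3 lower for nitrate, 1 higher for ammonium); as the tables are treated as picked on these samples, they are not taken as independent evidence of direction. NRT1.8 (AT4G21680), which retrieves nitrate from the xylem, stood at 102 and 34.6 in water and 37.2 and 43.9 with 2,5-D (adjusted p = 0.233), and SLAH3 (AT5G24030), a nitrate-permeable anion channel, at 61.8 and 22.8 in water and 32.5 and 32.8 with 2,5-D (adjusted p = 0.636). For both, the spread lay between the water libraries, and the direction turned with the water library left out: without water replicate 1 the log2 changes were 0.22 and 0.50, and without water replicate 2 -1.32 and -0.90. AMT2;1 (AT2G38290), the ammonium transporter of a separate subfamily, was at 34.0 ± 3.29 in water and 40.1 ± 4.81 with 2,5-D (adjusted p = 0.255). NRT2.6 (AT3G45060, 2.28 and 1.01 in water and 1.77 and 2.4 with 2,5-D, adjusted p = 0.380) changed sign without water replicate 2 (log2 change -0.10 against 0.26), and NRT2.5 (AT1G12940), a high-affinity nitrate transporter of nitrogen-starved plants, was below the filter at 0.0800 and 0.12 in water and 0.260 and 0.12 with 2,5-D. SLAH1 was below the filter and untested without water replicate 2. Nitrate genes higher numbered 3 without water replicate 1. AMT1;1 (adjusted p = 0.0581) missed the threshold without 2,5-D replicate 2. A fit with a library left out takes its spread from the other group alone, so its adjusted p is a rough guide.

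In shoots none of the transport genes passed the threshold over all tested genes in limma, but several stood apart from water in both libraries. SLAH3 was at 15.4 and 31.1 in water and 82.1 and 103 with 2,5-D (log2 change 2.02, SE 0.40, adjusted p = 0.0524). NRT1.8 was at 55.7 and 34.9 in water and 99.5 and 139.5 with 2,5-D (log2 change 1.4, SE 0.33, adjusted p = 0.0555), and NRT2.5 at 11 and 12.3 in water and 42.0 and 28.2 with 2,5-D (log2 change 1.49, SE 0.24, adjusted p = 0.0524). AMT2;1 was at 50.5 ± 7.87 in water and 81.5 ± 4.67 with 2,5-D (adjusted p = 0.0665) and AMT1;1 at 136 ± 22 in water and 184 ± 8.76 with 2,5-D (adjusted p = 0.150). NRT2.1 was low, at 0.25 and 1.44 in water and 2.39 and 1.57 with 2,5-D (adjusted p = 0.210). NRT1.5 (16.0 ± 4.21 in water and 13 ± 3.12 with 2,5-D) and NRT1.9 (4.84 ± 0.785 in water and 4.18 ± 0.714 with 2,5-D) overlapped between groups, with adjusted p = 0.445 and 0.474. NRT2.6 (0.0700 and 0.0700 in water and 0.50 and 1.1 with 2,5-D) and SLAH1 (0.280 and 0.180 in water and 0.150 and 0.220 with 2,5-D) were below the filter. Adjusted over the list alone, 3 of 6 tested nitrate genes (SLAH3, NRT1.8 and NRT2.5) and 1 of 2 ammonium genes (AMT2;1) were higher. The count over all genes rested on the shoot water pair: it was 5 without water replicate 1, 6 without water replicate 2 and 1 (NRT2.5) with equal medians.

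**Figure D1:**
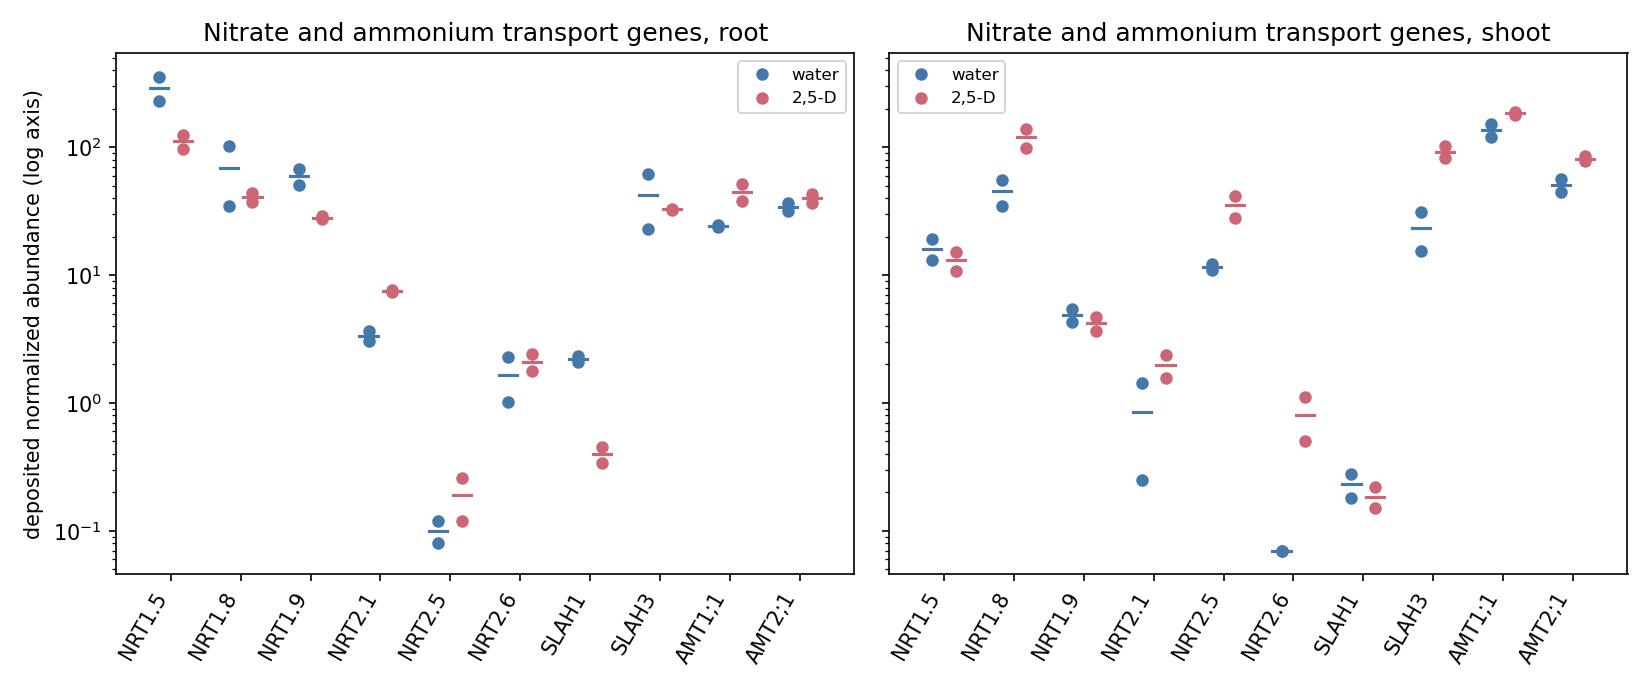
Deposited abundance (log axis) of the listed nitrate and ammonium transport genes in root and shoot libraries; points are single libraries (2 per group) and bars are means. In root, NRT1.5, NRT1.9 and SLAH1 lie lower with 2,5-D and NRT2.1 and AMT1;1 higher; in shoot, SLAH3 lies at 92.7 with 2,5-D and 23.3 in water, where no gene passed the threshold.

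In root, small heat shock proteins, which keep unfolding proteins from clumping, were among the genes that rose most with 2,5-D. HSP21 (AT4G27670), the chloroplast form, rose from 0 and 0.260 in water to 17.3 and 10.6 (log2 change 3.70, SE 0.24, adjusted p = 1.69e-05). The log2 changes were 3.51 for HSP22 (AT4G10250), 3.25 for the HSP20-like chaperone AT1G52560, 3.09 for HSP17.4 (AT3G46230) and 3.01 for HSP17.6C (AT1G53540). AT2G38240, a 2-oxoglutarate-dependent oxygenase, rose from 10.4 ± 3.49 to 136 ± 21.2 (log2 change 3.62). PSK6 (AT4G37720), a precursor of the growth peptide phytosulfokine, rose from 1.94 ± 0.827 to 33.6 ± 1.39 (log2 change 3.59). The aspartyl protease AT5G48430 (log2 change 3.11) completed the 8 largest rises.

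The 8 largest falls in root included cell wall proteins. AT3G22970, of unknown function, fell from 41.8 ± 14.4 to 6.96 ± 1.1 (log2 change -2.39, SE 0.23, adjusted p = 8.17e-05). The expansins EXPA15 (AT2G03090) and EXPA14 (AT5G56320), which loosen cell walls, fell by 1.8 and 1.78 on the log2 scale, and the β-xylosidase BXL2 (AT1G02640) by 2.0. The calcium-binding protein gene AT3G10190 had a log2 change of -2.3, the transcription factor MYB59 (AT5G59780) of -2.04, the E6-like protein gene AT1G03820 of -1.9 and the receptor kinase BAM3 (AT4G20270) of -1.79. Over the root table, limma called 2143 of 3487 tested genes, 1360 higher and 783 lower, among listed genes. By at least 1 on the log2 scale, 460 rose and 223 fell. Rescaling to equal medians moved all root changes by -0.11 and gave 1042 higher and 897 lower (370 and 358 by at least 1). The balance turned with the length trend removed, with 934 higher and 1004 lower (269 and 418 by at least 1). The count was 1093 without 2,5-D replicate 1 and 1313 without 2,5-D replicate 2.

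All 13 tested heat shock genes rose in root. HSP17.6II (AT5G12020) went from 3.67 ± 0.156 to 35.6 ± 7.05 (log2 change 2.96), and HSP23.6 (AT4G25200), a mitochondrial form, had a log2 change of 2.96. Of 20 genes of xenobiotic detoxification, 17 rose and 0 fell. The glutathione transferase GSTU3 (AT2G29470) rose from 3.94 ± 0.573 to 20.4 ± 0.283 (log2 change 2.1) and the oxophytodienoate reductase OPR1 (AT1G76680) from 131 ± 9.47 to 478 ± 2.47 (log2 change 1.87). The cytochromes P450 CYP81D11 (AT3G28740) and CYP81D8 (AT4G37370) rose by 2.04 and 1.68 on the log2 scale. Of 6 hypoxia genes, 3 rose and 0 fell, with the ERF factor HRE2 (AT2G47520) going from 118 ± 8.84 to 443 ± 64.6 (log2 change 1.9) and SRO5 (AT5G62520) at a log2 change of 0.91. Of 8 genes of abscisic acid, cold and drought, 7 rose and 0 fell. Their log2 changes included 1.8 for the dehydrin RAB18 (AT5G66400), 1.34 for KIN1 (AT5G15960), 1.16 for KIN2 (AT5G15970) and 0.84 for the NAC factor RD26 (AT4G27410). Counts adjusted over the list alone equalled those over all genes in these 4 lists. Without 2,5-D replicates 1 and 2 in turn, 11 and 11 xenobiotic and 4 and 4 abscisic acid genes rose, and without water replicate 2, 6 hypoxia genes did. SRO5 (adjusted p = 0.0612) missed the threshold without 2,5-D replicate 1. There the spread came from the water pair alone.

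Jasmonate genes rose in root, 11 of 13, and 0 fell. Among them were genes of jasmonate synthesis: the allene oxide cyclase AOC1 (AT3G25760) rose from 16.4 ± 2.69 to 81.8 ± 1.7 (log2 change 2.25), its near-identical neighbour AOC2 (AT3G25770) had a log2 change of 1.59, and the lipoxygenases LOX3 (AT1G17420) and LOX4 (AT1G72520) had 1.37 and 1.03. Of 11 salicylate and immunity genes, 5 rose and 1 fell. The glutaredoxin GRXC9 (AT1G28480, log2 change 1.43) and the transcription factors WRKY38 (AT5G22570, 1.37) and WRKY33 (AT2G38470, 0.69) rose. CYP79B2 (AT4G39950), which makes an indole precursor of camalexin and glucosinolates, fell (-0.62). Of 7 ethylene genes, 2 rose and 3 fell, with the synthesis enzyme ACS2 (AT1G01480) at a log2 change of 1.32 and the transcription factor ERF104 (AT5G61600) at -1.2. Counts adjusted over the list alone were equal to these. Leaving out 2,5-D replicate 1 gave 5 jasmonate and 2 immunity genes higher, with 1 ethylene gene higher and 1 lower. Leaving out 2,5-D replicate 2 gave 6 jasmonate, 2 immunity and 1 ethylene genes higher and 1 ethylene gene lower. Immunity genes higher numbered 8 without water replicate 1, 3 without water replicate 2 and 3 with equal medians. WRKY33 (adjusted p = 0.10) and CYP79B2 (0.136) missed the threshold without 2,5-D replicate 1. WRKY33 (adjusted p = 0.0649) and CYP79B2 (0.0857) missed the threshold without 2,5-D replicate 2. In both fits the spread came from the water pair alone.

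Most tested genes of cell wall loosening fell in root, as did the 3 tested root tissue markers, which act in the Casparian strip. Of 7 expansin and XTH genes, 0 rose and 6 fell, with EXPA4 (AT2G39700) going from 127 ± 42.6 to 45.8 ± 2.76 (log2 change -1.41) and EXPA17 (AT4G01630) at -1.28. Of 3 genes of auxin synthesis and transport, 0 rose and 2 fell, and the auxin efflux carrier PIN3 (AT1G70940) went from 26.1 ± 1.46 to 14.6 ± 1.75 (log2 change -0.80). Of 4 auxin response genes, the repressor IAA4 (AT5G43700) fell (log2 change -1.42) and the auxin-conjugating enzyme GH3.1 (AT2G14960) rose (0.56). Of 5 cytokinin response genes, 0 rose and 4 fell. Among these were ARR6 (AT5G62920, log2 change -1.34) and ARR4 (AT1G10470, -0.76), type-A response regulators that damp cytokinin signalling. All 3 tested root tissue markers fell, CASP1 (AT2G36100) from 71.3 ± 5.61 to 37.7 ± 6.05 (log2 change -0.91), CASP2 (AT3G11550) by 0.94 and ESB1 (AT2G28670), named after its value was seen, by 0.91 on the log2 scale. These build the Casparian strip, the barrier of the endodermis. Counts adjusted over the list alone were again equal. Cytokinin genes lower numbered 2 without 2,5-D replicate 1 and 1 without replicate 2. Without 2,5-D replicate 1, 1 root marker fell, and without water replicate 2, 3 auxin response genes rose. Without water replicate 1, 1 gene of auxin synthesis and transport rose. ARR4 (adjusted p = 0.0661) and CASP1 (0.0613) missed the threshold without 2,5-D replicate 1. GH3.1 (adjusted p = 0.216) and ARR4 (0.0579) missed the threshold without 2,5-D replicate 2. GH3.1 missed the threshold with equal medians (adjusted p = 0.0544) and with the length trend removed (adjusted p = 0.0517). In the fits without a 2,5-D replicate, the spread came from the water pair alone.

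Of 6 genes of nitrogen assimilation tested in root, 2 rose and 0 fell, and 4 did not pass. The asparagine synthetase ASN1 (AT3G47340) rose from 80.3 ± 7.14 to 137 ± 23.3 (log2 change 0.76) and the glutamate dehydrogenase GDH3 (AT3G03910) from 0.885 ± 0.0212 to 2.58 ± 0.0707 (log2 change 0.93). Of 11 nitrate signalling genes, 2 rose and 3 fell. LBD37 (AT5G67420), a repressor of nitrogen-responsive genes, fell from 24.2 ± 4.2 to 10.8 ± 0.0141 (log2 change -1.08), and CEPR1 (AT5G49660), a receptor of nitrogen-demand peptides, fell by 1.02 on the log2 scale. Of 4 sulfur genes, 0 rose and 3 fell, among them the sulfate-reducing enzyme APR1 (AT4G04610), from 130.5 ± 21.9 to 55.6 ± 4.78 (log2 change -1.21), and LSU2 (AT5G24660, -1.16). Of 8 phosphate starvation genes, 5 rose and 0 fell, including the non-coding RNAs IPS1 (AT3G09922, log2 change 0.64) and AT4 (AT5G03545), the latter from 2065 ± 222 to 3016 ± 379.8 (log2 change 0.54). The number that rose was 1 with equal medians, 0 with the length trend removed, 0 without 2,5-D replicate 1, 1 without 2,5-D replicate 2 and 3 without water replicate 1. Of 5 iron deficiency genes, 1 rose and 2 fell, with the nicotianamine synthase NAS4 (AT1G56430) at a log2 change of -1.16 and the transcription factor PYE (AT3G47640) at 0.76. Counts adjusted over the list alone were the same for these 5 lists. The nitrogen assimilation calls changed with the library left out, and without water replicate 1 they went in both directions. Nitrate signalling genes lower numbered 6 without water replicate 1, 2 without either 2,5-D replicate and 5 with equal medians, and those higher 4 without water replicate 2 and 1 without either 2,5-D replicate. Iron deficiency genes lower numbered 1 without either 2,5-D replicate or without water replicate 2. PYE (adjusted p = 0.0798), IPS1 (0.116) and AT4 (0.165) missed the threshold without 2,5-D replicate 1. ASN1 (adjusted p = 0.127) and IPS1 (0.12) missed the threshold without 2,5-D replicate 2. AT4 (adjusted p = 0.0565) missed the threshold with equal medians. IPS1 (adjusted p = 0.235) and AT4 (0.178) missed the threshold with the length trend removed. Fits without a 2,5-D replicate took their spread from the water pair alone.

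The sucrose exporter SWEET11 (AT3G48740) fell in root (log2 change -1.42) and the sugar starvation gene SEN1 (AT4G35770) rose (0.92), in a sugar list of 4 tested genes where 1 rose and 2 fell. The glucosinolate enzymes CYP79F2 (AT1G16400, log2 change -1.0) and SUR1 (AT2G20610, -0.70) fell, 2 of 3 tested. Of 4 flavonoid genes, chalcone synthase, CHS (AT5G13930, -0.67), fell and its regulator MYB12 (AT2G47460, 0.64) rose. Neither the 1 iron storage gene nor the 1 clock gene tested passed. Of 12 photosynthesis genes, 1 fell, the antenna gene LHCB2.1 (AT2G05100, log2 change -0.50, named after its value was seen), and 0 were lower adjusted over the list alone. The other counts adjusted over the list alone were equal to those over all genes. Photosynthesis genes lower numbered 9 without water replicate 1, 0 without water replicate 2 or either 2,5-D replicate, and 6 with the length trend removed. Sugar genes lower numbered 1 without either 2,5-D replicate and those higher 2 without water replicate 1, where the iron storage gene also rose. Glucosinolate genes lower numbered 0 and 1 without 2,5-D replicates 1 and 2. CYP79F2 (adjusted p = 0.0904), SUR1 (0.121) and CHS (0.0924) missed the threshold without 2,5-D replicate 1. SUR1 (adjusted p = 0.0666), CHS (0.0910) and MYB12 (0.241) missed the threshold without 2,5-D replicate 2. MYB12 missed the threshold without water replicate 1 (adjusted p = 0.0756), with equal medians (adjusted p = 0.0713) and with the length trend removed (adjusted p = 0.262). Fits with a library left out took their spread from the other group's pair alone.

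**Figure D2:**
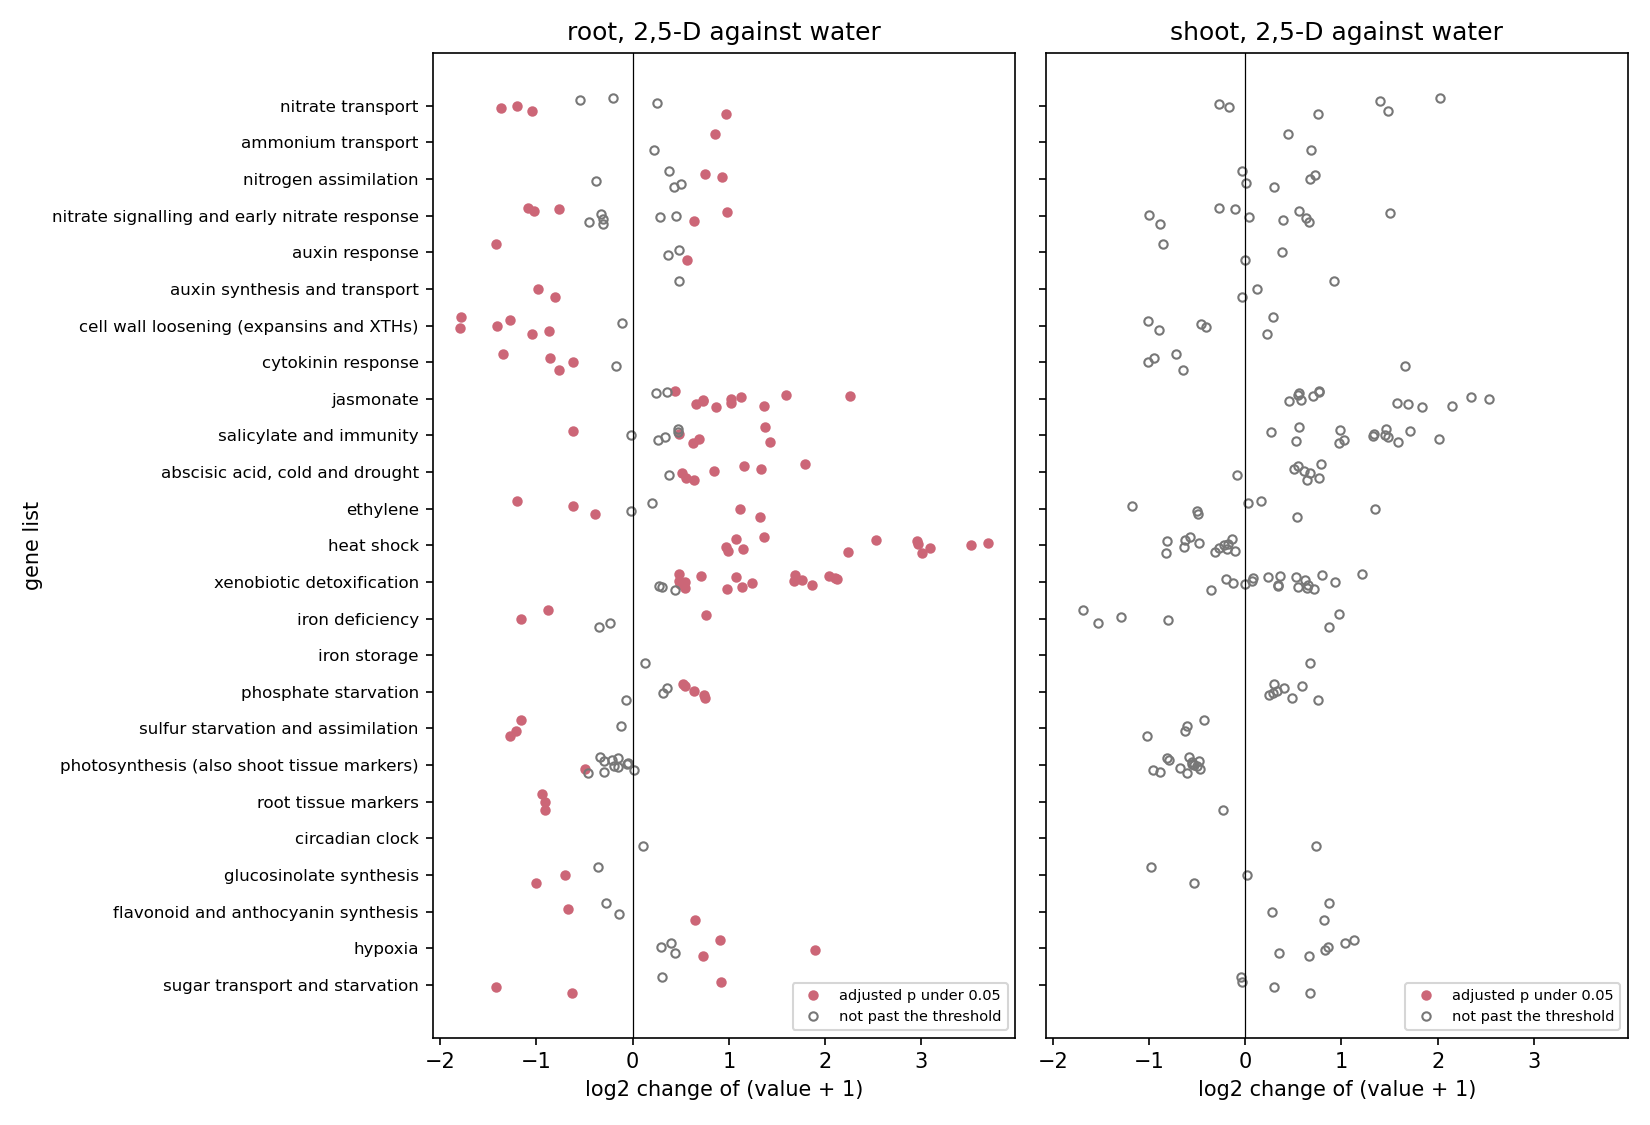
Log2 change of (value + 1), 2,5-D against water, for the tested members of the 25 gene lists in root and shoot; each point is a gene, filled where limma's adjusted p was under 0.05. In root the 13 heat shock genes all lie above 0 and 6 of 7 expansin and XTH genes are called lower; in shoot no gene was called.

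In shoots, light-harvesting and Rubisco transcripts lay lower with 2,5-D and immune transcripts higher, though no gene passed the threshold over all tested genes. The antenna gene LHCB1.1 (AT1G29920) was at 2417 and 2716 in water and 1219.9 and 1427 with 2,5-D (log2 change -0.96, adjusted p = 0.0524), and LHCB1.5 (AT2G34420) had a log2 change of -0.67 (adjusted p = 0.0524). The small Rubisco subunit gene RBCS1B (AT5G38430) was at 3587 and 2793 in water and 1623 and 2002 with 2,5-D (log2 change -0.81, adjusted p = 0.0555). All 13 photosynthesis genes in the table had both 2,5-D libraries below both water libraries. The salicylate exporter EDS5 (AT4G39030) was at 12.7 and 12.8 in water and 50.8 and 38.4 with 2,5-D (log2 change 1.72, adjusted p = 0.0524). The flagellin-responsive kinase FRK1 (AT2G19190) was at 2.06 and 2.1 in water and 14.5 and 9.06 with 2,5-D (log2 change 2.02, adjusted p = 0.0524), and the camalexin enzyme CYP71A13 (AT2G30770) had a log2 change of 1.49 (adjusted p = 0.0524). All 14 salicylate and immunity genes lay above water in both libraries, and 4 of them were over 2-fold higher in water replicate 2 than in replicate 1. Chance separates 2 libraries from 2 in 33.3% of genes, either way, but 75.7% of all listed genes were separated in shoot, 1836 higher and 957 lower. Adjusted over the list alone, 13 photosynthesis genes were lower and 4 immunity genes higher, in tables treated as picked on these samples.

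In shoot, the nicotianamine synthase NAS1 (AT5G04950) was at 31.7 and 29.0 in water and 9.72 and 7.84 with 2,5-D (log2 change -1.69, adjusted p = 0.0524). The iron-signalling peptide gene IMA2 (AT1G47395) was at 2.53 and 4.61 in water and 0.770 and 0.350 with 2,5-D (log2 change -1.53, adjusted p = 0.0524). Of 6 iron deficiency genes, 1 was higher and 4 were lower adjusted over the list alone. Nitrite reductase, NIR1 (AT2G15620), was at 151 ± 18.8 in water and 241 ± 11.6 with 2,5-D (adjusted p = 0.0620), and the nitrogen-use regulator BT2 (AT3G48360) at 60.2 ± 5.59 in water and 29.6 ± 1.24 with 2,5-D (adjusted p = 0.0524). Adjusted over the list alone, 3 nitrate signalling genes were higher and 2 lower, and 0 assimilation genes were called. CKX5 (AT1G75450), a cytokinin-degrading oxidase, was at 2.76 and 3.64 in water and 15.0 and 9.80 with 2,5-D (adjusted p = 0.0524), in a cytokinin list with 1 higher and 3 lower adjusted over the list alone. Of 13 jasmonate genes, 6 were over 2-fold higher and 2 over 2-fold lower in water replicate 2 than in replicate 1. LOX3 was at 24.7 and 212 in water and 369 and 289.6 with 2,5-D (adjusted p = 0.203), and the repressor gene JAZ7 (AT2G34600) at 11 and 125 in water and 203 and 190.5 with 2,5-D (adjusted p = 0.206). Heat shock genes had a median log2 change of -0.32, with 3 of 13 separated lower, and 7 were over 2-fold lower in water replicate 2 than in replicate 1 (median -1.17). Of the remaining lists, 2 flavonoid genes, 1 iron storage gene and 1 clock gene were higher and 1 cell wall gene lower, adjusted over the list alone, and no genes in the others.

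Over the whole shoot table limma called 0 of 3376 tested genes at an adjusted p of 0.05 (smallest adjusted p = 0.0524). With library weights the count was also 0, but each shoot water library got the same weight, 0.448. The weights thus could not set either water library below the other. An unadjusted p under 0.05 was reached by 1664 genes, 1016 higher and 648 lower. The shoot water pair had 551 of these tested genes over 2-fold apart. Without water replicate 1 the count was 2121 (1435 higher, 686 lower), and without water replicate 2 it was 2480 (1620 higher, 860 lower), with the lone water library assumed to vary like the 2,5-D pair. Rescaling to equal medians moved all shoot changes by -0.40 and called 62 higher and 483 lower. As the medians are those of genes treated as picked for differing, this shift may remove real change, and neither scale is settled as right. Relative to that shift, the median log2 change was -0.98 for photosynthesis genes, -0.58 as deposited. It was 0.93 for immunity genes (1.33 as deposited) and 0.68 for nitrate transport genes (1.08 as deposited). For nitrogen assimilation genes it turned from 0.29 as deposited to -0.11, and for nitrate signalling genes from 0.22 to -0.18.

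**Figure D3:**
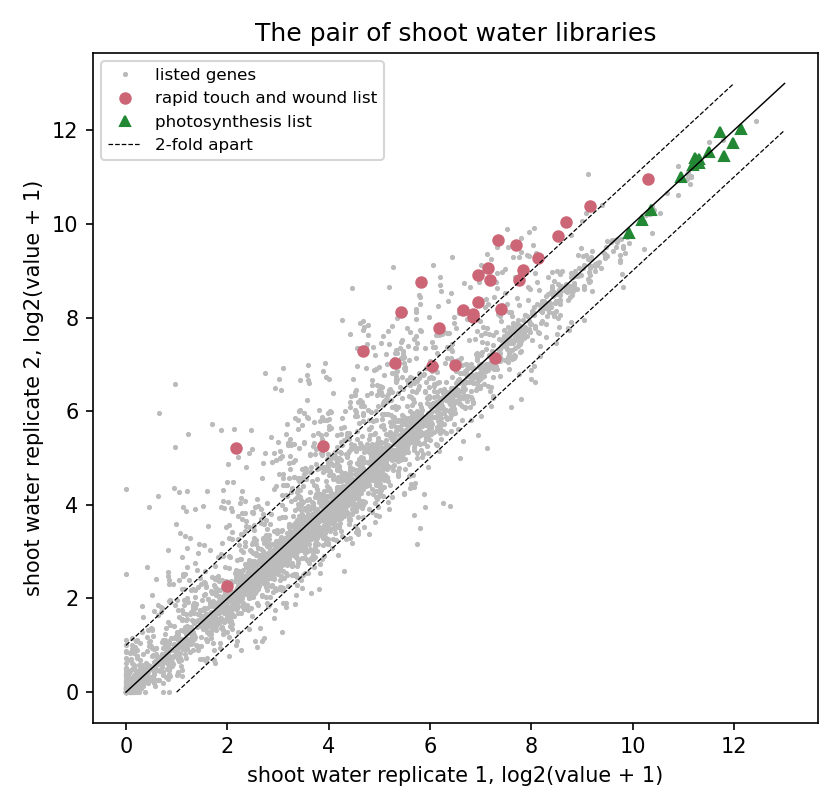
Log2(value + 1) of the listed genes in shoot water replicate 1 (x axis) and replicate 2 (y axis), with dashed lines at 2-fold apart. The 28 genes of a rapid touch and wound list (red), written after this difference was seen, lie a median 1.35 higher in replicate 2 on the log2 scale, and the photosynthesis genes (green) lie near the diagonal.

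Root and shoot responses were set side by side over the 3215 genes tested in both. The heat shock genes HSP21, HSP22 and HSP17.6C, which rose in root, had log2 changes of -0.48, -0.22 and -0.83 in shoot. Their root minus shoot differences were 4.18, 3.73 and 3.84 (adjusted p = 0.0195, 0.0253 and 0.0212 for the tissue by treatment term in limma). EXPA14 (-2.07, adjusted p = 0.0169), SWEET11 (-1.72, adjusted p = 0.0169) and CYP79B2 (-1.61, adjusted p = 0.0169) differed with the other sign. None of the transport genes passed that test, with NRT1.9 (adjusted p = 0.0532), SLAH3 (0.0585) and NRT1.8 (0.0850) nearest to it. These 3 passed when either shoot water library was left out, and 4 of 7 transport genes, with NRT1.5, passed without replicate 1. Without replicate 1 their adjusted p was 0.0181 (NRT1.9), 0.0305 (SLAH3), 0.0175 (NRT1.8) and 0.0193 (NRT1.5), and without replicate 2 it was 0.0458, 0.00397 and 0.0472 for the first 3, with 0 past the threshold with equal medians. Calls shared by both tissues numbered 0, as limma called no shoot gene, so no overlap test was made. Of 1885 genes called in root, 1526 (81.0%) had the same sign in shoot. Groups were apart in both tissues for 2160 genes, and 80.7% of these went the same way, against 53.1% from the marginal counts. Of these genes 1147 were higher in both tissues, 597 lower in both, 145 higher in root and lower in shoot, and 271 the reverse. Log2 changes correlated across the 3215 genes tested in both tissues at r = 0.439, where genes are not independent replicates. The tissue by treatment term, planned for raw counts only and fitted with 1 spread per gene for all groups, passed the threshold for 936 genes. The count was 292 with equal medians, 1344 without shoot water replicate 1 and 1700 without shoot water replicate 2.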

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

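All tests in this part were chosen after the results were seen. The treatment effect differed between root and shoot (adjusted p under 0.05 for the tissue by treatment term in limma over the 8 libraries) for 23 of the genes named in the text. The small heat shock genes had the largest root minus shoot differences of log2 change: HSP21 4.18, HSP22 3.73, HSP17.4 3.37, HSP17.6C 3.84, HSP17.6II 3.77 and HSP23.6 3.14. The same sign was seen for AT2G38240 2.6, AOC1 1.55, GSTU3 2.32, OPR1 1.22 and LHCB1.1 0.97. The root change was the more negative for AT3G10190 -1.57, BXL2 -1.83, AT1G03820 -1.01, EXPA15 -1.39, BAM3 -1.86, EXPA14 -2.07, CEPR1 -1.58, PIN3 -0.76, CYP79B2 -1.61, CHS -0.94, SWEET11 -1.72 and CKX5 -1.83. Adjusted p ran from 0.0169 to 0.0485 on the deposited scale. With equal medians the term missed the threshold for AT3G10190, AT1G03820, EXPA15, PIN3 and CHS (adjusted p = 0.0722 to 0.155).

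The 2 shoot water libraries differed: of 3376 tested genes, 551 were over 2-fold apart, 468 higher and 83 lower in replicate 2, and among lists fixed beforehand 7 of 13 heat shock (median -1.17), 3 of 6 hypoxia (median -0.99) and 5 of 19 xenobiotic genes (median -0.47) were over 2-fold lower, and 6 of 13 jasmonate genes higher. A difference in scaling as the cause is argued against, since it would move all genes 1 way and the median log2 difference over all tested genes was -0.0385. Replicate 2 correlated across genes more closely with the 2,5-D libraries (r = 0.963 and 0.969) than with replicate 1 (0.946). A 2,5-D library under a water label is argued against by the 5 photosynthesis genes that separated the groups in root too. In replicate 2 they lay a median 0.62 above the 2,5-D mean on the log2 scale. All 13 lay a median 0.61 above it (0.59 in replicate 1), but the rest may be listed only because shoot separated them. A candidate explanation that stays open is rapid touch or wound induction at harvest, since 22 of 28 genes of a rapid response list were over 2-fold higher in replicate 2 (median 1.35, quartiles 1.1 and 1.86), above all 10000 random lists matched on expression (highest 1.28), though this list was written after the first such genes were seen and without them, and the lower lists were not tested against it. The same genes lay a median 1.62 higher with 2,5-D than in water replicate 1 and 0.30 higher than in water replicate 2. The median over all tested genes was 0.34 and 0.28 higher in these comparisons. In root the same genes lay 0.53 higher with 2,5-D (27 of 28 positive), against 0.26 for all tested genes. How much of their shoot change comes from the treatment is thus open. The design names no biological difference within the shoot water pair that could be tested.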

How the results depend on the processing

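Library weights, the length trend and the tissue by treatment counts were chosen after seeing the data; the cause of each shift was not tested unless stated. Root calls numbered 1938 to 2204 under a pseudocount of 0.1, no filter, equal medians, library weights, length trend removal and the replicate block (2185); the count was 683 with a log2 change of at least 1, a stricter rule by construction. The fold limit left 3 of 5 root transport calls and 50 of 105 calls in the other lists. Leaving out 1 library, where the lone library is taken to vary like the other group, gave 1093 to 2512 root calls, 4 to 7 root transport calls and 62 to 121 in the other lists. The lowest counts came without 2,5-D replicate 1 for all genes and the other lists and without 2,5-D replicate 2 for transport. Equal medians raised the shoot counts from 0 to 545 genes, 1 transport gene, 26 in the other lists and 219 calls shared with root. Leaving out 1 library gave 0 to 2480 shoot calls, 0 to 6 transport, 0 to 108 in the other lists and 0 to 1010 shared; the counts above 0 all came from leaving out a shoot water library, which leaves the spread to the closer 2,5-D pair. The tissue by treatment count was 292 with equal medians and 1344 to 1700 without a shoot water library. Log2 changes that changed sign when a root water library was left out were those of NRT1.8 (-1.32 to 0.22), NRT2.6 (-0.10 to 0.61) and SLAH3 (-0.90 to 0.50). The 72 named root results kept their side of the threshold under the pseudocount, no filter, the block and library weights. So did the 21 in shoot under these but the block. Direction was kept too, but only the pseudocount could have changed it. The other settings leave each log2 change as it was by construction. Same-numbered root libraries did not deviate together (r = -0.0501, 2 pairs), and the block ended no call of a named root gene. SLAH1 in root was untested without water replicate 2, where its mean was under the filter. No paired analysis was possible for shoot because both 2,5-D columns carry the same replicate number. The planned set tests and alternatives for counts were not run. Depth limits values near 1 read, such as NRT2.6 in shoot and NRT2.5 in root.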

Other observations

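The families below and the length test of ribosomal genes in shoot were chosen after the results were seen. In root, of 7 aquaporins, which let water cross membranes, 6 fell with 2,5-D, among them PIP1A (AT3G61430) from 404 ± 36.7 to 185 ± 1.18 (log2 change -1.1) and PIP1B (AT2G45960, log2 change -0.78), while the seed-type TIP3;1 (AT1G73190) rose (1.79). Of 7 laccases in root, several of which polymerize lignin, 6 fell: IRX12 (AT2G38080) from 14.2 ± 0.721 to 5.17 ± 0.318 (log2 change -1.3), LAC3 (AT2G30210, -1.56), LAC11 (AT5G03260, -1.14) and LAC17 (AT5G60020, -0.97), with TT10 (AT5G48100), which oxidizes seed coat flavonoids, higher (0.63). Of 27 WRKY transcription factors in root, which act in defence, 22 rose and 1 fell. With equal medians in root 6 aquaporins and 6 laccases fell, 0 laccases rose (0 also with the length trend removed, and 0 without 2,5-D replicate 2) and 17 WRKY genes rose, among listed genes. Without 2,5-D replicate 1, 1 aquaporin fell and 10 WRKY genes rose, and without 2,5-D replicate 2, 4 aquaporins fell and 12 WRKY genes rose.

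In shoot no member of any family here passed the threshold in limma as deposited. With equal medians, 13 kinase-annotated genes were higher and 4 lower, 5 immune receptor genes were higher, and 8 histone, 2 aquaporin and 1 WRKY genes lower. Most WRKY genes lay the other way: of 28, 23 were separated higher and 1 lower in shoot. Their median log2 change was 0.64 (0.24 with equal medians, 0.64 with the length trend removed). Of 46 immune receptor genes of the TIR and NBS-LRR type, 45 had both 2,5-D libraries above both water libraries (median log2 change 0.85, 0.45 with equal medians, 0.25 with the length trend removed). Of 225 genes picked by the words kinase and protein in their annotation, not all of them protein kinases, 164 were separated higher and 22 lower (medians 0.77, 0.37 and 0.29). Of 16 histone genes, 15 were separated lower (medians -0.59, -0.99 and -0.32). Chance separates 33.3% of genes, but of all listed genes 75.7% were separated in shoot, 1836 higher and 957 lower. Median exonic length was 4170 bases for the immune receptor genes, 2598 for the kinase-annotated genes and 802 for the histone genes. Among all tested shoot genes the longest of 5 length bins had a median log2 change of 0.67 and the shortest -0.47. The trend with length may thus account for much of the change in these families.

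Of 81 ribosomal protein genes, 29 fell and 0 rose in root, where 70 were separated lower and 2 higher. The number that fell was 56 with equal medians, 77 with the length trend removed, 0 without 2,5-D replicate 1, 1 without 2,5-D replicate 2, 51 without water replicate 1 and 45 without water replicate 2. In shoot 80 were separated lower and 1 higher, with 0 called as deposited and 63 lower with equal medians, and all photosynthesis genes were separated lower there.

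Lower values of ribosomal and photosynthesis genes in shoot stood beside a trend with length. Shoot changes followed exonic length across genes (Spearman 0.381, median -0.47 in the shortest and 0.67 in the longest of 5 length bins), while root changes ran the other way (Spearman -0.196, 0.34 in the shortest and -0.06 in the longest bin) and the root 2,5-D replicates differed with length too (0.435). With each library's length trend removed, the median change was -0.53 for photosynthesis genes in shoot (before -0.58), -0.30 for ribosomal genes in shoot (before -0.59, quartiles -0.44 and -0.23) and -0.68 for ribosomal genes in root (before -0.36). These values argue against a length bias as the whole cause for photosynthesis genes in shoot. For ribosomal genes in root, the direction of the trend argues against it, as the shortest bin there rose while these short genes fell. Removing that trend could only lower them further, so the -0.68 is no separate test. For ribosomal genes in shoot (median 859 exonic bases) the values cannot decide. The shortest bin in shoot still had a median of -0.13 after removal, and the trend may account for much of the change of ribosomal genes there. The trend was fitted to listed genes that include these families, so its removal may also take out real change tied to length. An effect of 2,5-D on these genes stays open, as does a change specific to these libraries.

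The listed genes themselves carry a pattern. Only 2 of them separated the groups in neither tissue, where 1640.4 would by chance, with 896 separated in root alone and 633 in shoot alone. Shares of higher and lower genes, the correlation between tissues and any trend across genes are those of the listed genes; genes outside the tables were not analysed here.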
